A study of Mus musculus with 8 samples.

How the data were processed

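Mouse endometrium was profiled 8 h after coitus on 8 arrays, 4 from females mated with intact males and 4 from females mated with SVX/VAS males. The design text of the series states that RNA of 16 females per group was combined into 4 independent pools of 4 females, so that the spread between arrays of a group is a spread between pools, not between single animals. Per the labels' protocols, the endometrium was scraped from the opened uterus, the muscle layer was discarded, and the RNA integrity number was above 7. The design text states that 300 ng of total RNA were labelled for Affymetrix Mouse Gene 2.0 ST arrays.

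The deposited value table holds log2 expression, 1 row per transcript cluster and 1 column per array. Per the design text, the authors imported the scans into Partek Genomics Suite 6.6 with RMA background correction, a correction for GC content and mean summarization of probes. The submitters' processing notes also name Affymetrix Expression Console, without saying which tool made the values. The log2 scale was checked against the authors' deposited comparison table: its ratios equal the difference of group means of the value table, with a largest deviation of 5.95e-05 on the log2 scale. That table gives, per the file headers, a ratio and a signed fold change of intact over SVX/VAS and an unadjusted p-value for each row. The design text calls the authors' test a t-test and sets limits of 0.05 for its p-value and 1.50 for the fold. Its p-values match those of a pooled-variance test recomputed from the values, with a largest deviation of 0.00147 in log10. Detection calls, background levels and scan dates are not given in the sources used here, so neither signal over background nor a scan batch could be tested. The genome build is also not given in the sources used here, and no coordinates are printed; chromosomes and bands are those of the deposited annotation. Any normalization across arrays makes the values of an array depend on the others, and summarization by the mean lets 1 bright probe or a probe shared by related genes raise a cluster.

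Gene symbols come from the deposited table. Of 41345 rows, 26989 carried 1 symbol, 48 several and 14308 none. Symbols were brought up to date through a RefSeq gene table (assembly GRCm38.p6, used for names only): 19442 rows matched by accession, 5707 by symbol and 746 by synonym, 1142 did not match and kept the symbol of the file, and 2743 symbols changed. The rows name 24580 genes, 1666 of them with several rows. A gene with several rows is given by the row with the highest mean over all 8 arrays. Rows with several symbols or none were tested but not named. Control rows are not marked in the table, so all rows were tested, although the plan was to leave controls out.

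Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, without covariates, trend or robust estimation, and p-values were adjusted by the Benjamini-Hochberg method over all rows. An adjusted p under 0.05 was the threshold, with and without a change of at least 1.5-fold. Errors are SD over the 4 arrays of a group, SE of limma, or 95% confidence intervals of limma. Bootstrap intervals of the median of a gene list resample its genes, not the pools. They show the spread over genes and not the uncertainty of the difference between groups. The choices of tests, of 32 gene lists, of the rule for named genes and of the alternatives were made before the data were examined. Of 687 list members 677 were measured, and each list needed at least 5. Lists were tested with camera (preset correlation 0.01) on 1 row per gene and adjusted over the 32 lists; camera with an estimated correlation and fry were alternatives. The exact permutation test of each list mean over the 35 splits of the arrays was added after the data were seen. List members were counted by limma's p adjusted over all rows and adjusted over the list alone.

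The text names genes by a fixed rule. It takes, among genes with 1 symbol past the threshold whose groups do not overlap, the 15 with the largest rise and the 10 with the largest fall. From each list it takes up to 3 members called higher and up to 3 called lower over all rows, or, where none is called, the member with the smallest unadjusted p. It adds 19 immune genes fixed in advance. Some genes that the rule takes are left out of the text and of the plot of single genes, but not of the counts. The rule names Y-linked and male-tract genes only from their lists. No named gene had rows of opposite sign. In addition, 30 genes were taken up after their values were seen, because they passed over their list alone: Cxcl3, Cxcl10, Il18, Tgfb3, Tnfaip3, Tnip3, Bcl3, Nfkbie, Chil1, Nos2, Ptger4, Plat, Adamts1, Sprr2b, Padi4, Esr1, Ltbp2, Hsph1, Nr4a1, Fosb, Jun, Dbp, Cry2, Bhlhe41, Slfn4, Il1r2, Ly6g, Wnt7b, Tmprss2 and Krt18. The closing section describes 6 further lists that were also chosen then, and the members it names were likewise seen first.

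The fits and list tests were tested on simulated data for the comparison of intact with SVX/VAS, over 41345 clusters and 20 simulations with 200 changed clusters each. All changed clusters were drawn from those above the median level, and the noise was independent between clusters, unlike in the real arrays. The fits recovered 27.5% of these brighter clusters changed 1.5-fold, 67.4% of those changed 2-fold and 97.7% of those changed 4-fold, with 7.65 false calls on average. Lists of independent genes shifted in the simulation were called in 100% of cases.

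Alternatives were the replicate number as a block, quantile normalization, centring of each array on its median, rows above the median level, rows with 1 symbol, eBayes with trend and robust estimation, array weights, the methods' t-test, the authors' deposited table, leaving out each array in turn, and, for lists, an estimated correlation, fry and the mean of all rows of a gene. A fit with the mean of the stromal markers of each array as a covariate was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.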

Results

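Endometrial gene expression was measured in mice 8 h after coitus, on 8 Affymetrix Mouse Gene 2.0 ST arrays, which carry probes along the length of each transcript. The females were CBAF1, a cross of 2 inbred strains, and had mated with Balb/c males. In 1 group the males were intact, so that the females received seminal fluid. In the other the males were SVX/VAS, and per the labels mating took place without exposure to seminal fluid. Each group had 4 arrays, and each array held a separate pool of endometrial RNA from 4 females, 16 females per group. All values are log2 expression as the authors normalized it, and the number of arrays limits the precision. The arrays had medians between 5.35 and 5.41, and 41345 transcript clusters were measured, of which 26989 carried a single gene symbol. Pearson correlations between arrays, taken across clusters, lay between 0.971 and 0.984.

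The intact arrays varied more than the SVX/VAS arrays. The mean correlation of an array with the rest of its own group was 0.974 to 0.977 for intact and 0.982 to 0.983 for SVX/VAS. Intact replicates 3 and 4 correlated at least as closely with the SVX/VAS arrays (means of 0.974 and 0.980) as with the other intact arrays (0.974 and 0.976). Replicate 3 had the lowest array weight, 0.66, of all arrays. On the first principal component, which held 22.4% of the variance, replicate 4 had a score of 0.56, while the other intact arrays had scores of 28.3 to 37.6 and the SVX/VAS arrays scores of -20.8 to -27.7.

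The comparison of intact with SVX/VAS matings asked which endometrial transcripts differ when the male at coitus is intact rather than SVX/VAS. After intact matings, the endometrium held more transcript of Cxcl5, a chemokine that attracts neutrophils, of Il1b, which encodes the inflammatory cytokine interleukin 1 beta, and of Csf3, the growth factor of granulocytes. It also held more Sprr2d and Sprr2e, small proline-rich proteins of epithelial surfaces, more Peg10, an imprinted gene derived from a retrotransposon, and more of several enzymes of cholesterol synthesis, such as Idi1 and Sqle. Transcripts of the LIF receptor Lifr, the clock repressor Nr1d2 and the dipeptidases Cndp1 and Cndp2 were lower. In all, 34 of the 41345 clusters passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 21 higher and 13 lower in intact, and each of the 34 differed by at least 1.5-fold. In each of the 34, all 4 arrays of one group lay above all 4 of the other. Of all clusters, 8.17% showed such separation, against the 2.86% that chance gives. Of the 34, 30 carried a single gene symbol, 18 higher and 12 lower, and the other 4 carried none. At an unadjusted p of 0.05, 2122 clusters were higher and 2803 lower, where 2067.25 in all would be expected on average if no cluster differed.

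Among genes past the threshold, the largest rises were those of Sprr2d, Peg10, Sprr2e and Cxcl5. Sprr2d had a mean log2 value of 10.65 ± 0.43 (SD, n = 4) after intact matings and 8.04 ± 0.36 after SVX/VAS matings, a 6.12-fold difference (log2 difference 2.61, SE 0.24, limma adjusted p = 0.0102). Its neighbour in the deposited annotation, Sprr2e, on the same band of chromosome 3, rose 5.08-fold (log2 difference 2.35, SE 0.21, adjusted p = 0.0102). The Sprr2 genes are close copies of each other, so probes for one may also bind another, and the values of single members are uncertain. Peg10, on chromosome 6, rose 5.25-fold from 9.11 ± 0.50 to 11.50 ± 0.12 (adjusted p = 0.0102). Cxcl5, on chromosome 5, rose 4.66-fold, from 7.15 ± 0.19 to 9.37 ± 0.58 (SE of the log2 difference 0.26, adjusted p = 0.0325). Il1b rose 3.62-fold, from 4.96 ± 0.38 to 6.82 ± 0.42 (adjusted p = 0.0423). Csf3 rose 2.19-fold with little spread, from 6.41 ± 0.05 to 7.54 ± 0.12 (adjusted p = 0.00946). Ccnd1, which encodes cyclin D1, and Gsta4, a glutathione transferase, rose 1.82-fold and 1.79-fold (adjusted p = 0.0329 and 0.0209).

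Other rises were those of enzymes of sterol synthesis. Idi1, the isomerase that makes the building blocks of isoprenoids, had the smallest p of all clusters and rose 2.78-fold, from 5.80 ± 0.07 to 7.28 ± 0.14 (log2 difference 1.48, 95% confidence interval 1.25 to 1.70, adjusted p = 0.00462). Sqle, squalene epoxidase, rose 2.79-fold (log2 difference 1.48, SE 0.13, adjusted p = 0.0102). Hmgcs1, an early enzyme of the pathway, rose 2.63-fold (adjusted p = 0.02). Fdps and Mvd, of its middle steps, rose 2.21-fold and 2.10-fold (adjusted p = 0.0339 and 0.0163). Epithelial markers as a list had a median log2 difference of 0.16 and did not pass the list test (adjusted p = 0.309).

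Among the falls, Mettl7a1, a methyltransferase-like protein, was 2.46-fold lower, at 6.99 ± 0.27 after intact and 8.29 ± 0.20 after SVX/VAS matings (log2 difference -1.30, SE 0.16, adjusted p = 0.0329). Rasa4, which switches off Ras, and Sv2b, a vesicle glycoprotein, were 2.07-fold and 2.04-fold lower (adjusted p = 0.0429 and 0.0247). Nr1d2, a nuclear receptor that represses clock genes, was 1.97-fold lower, at 6.14 ± 0.19 and 7.11 ± 0.06 (adjusted p = 0.0258). Lifr, a subunit of the receptor for the implantation cytokine LIF, was 1.88-fold lower, at 8.34 ± 0.15 and 9.25 ± 0.10 (adjusted p = 0.0325). Tspan15, a tetraspanin, was 1.95-fold lower (adjusted p = 0.0258), and Dhrs4, a dehydrogenase, and Snx5, a sorting nexin, were 1.73-fold and 1.68-fold lower (adjusted p = 0.0429 and 0.0329). Cndp2 and Cndp1, which split dipeptides, were 1.86-fold and 1.64-fold lower (adjusted p = 0.0329 and 0.0362).

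**Figure D1:**
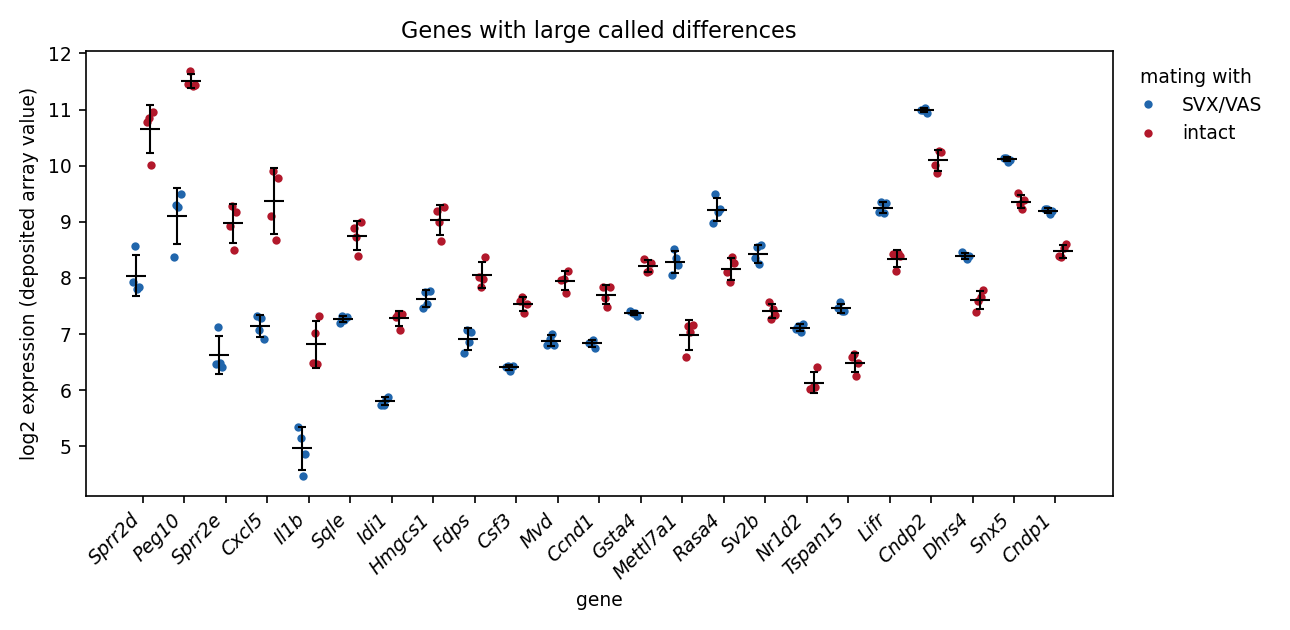
Log2 expression of each array for the genes of the largest rises and falls that the text names, SVX/VAS in blue and intact in red, with the mean and SD of 4 arrays in black; the x axis lists genes. The naming rule takes only genes whose groups do not overlap, as for Csf3 at 6.41 ± 0.05 and 7.54 ± 0.12.

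The naming rule takes only genes whose groups do not overlap, so a fit that leaves out 1 array cannot reverse their direction. Its 25 genes of largest rise or fall kept their direction in all 8 such fits, but not all kept an adjusted p under 0.05. The number that did was 1 without intact replicate 1, 2 without intact replicate 2, 20 without intact replicate 3 and 11 without intact replicate 4. It was 2, 8, 1 and 1 without SVX/VAS replicates 1, 2, 3 and 4. Over all clusters, the 34 became 2, 4, 50 and 21 without intact replicates 1 to 4, and 3, 9, 2 and 2 without SVX/VAS replicates 1 to 4. Lower clusters passed only without intact replicate 3 (9) and intact replicate 4 (10), and 0 lower ones passed in limma in the other 6 fits, where 4162 to 4340 clusters in both directions had an unadjusted p under 0.05. With the methods' t-test and Benjamini-Hochberg adjustment 10 clusters passed, 6 of them among the 34, and with the clusters above the median level tested alone 358 passed. In the authors' deposited table, 768 clusters had an unadjusted p under 0.05 and a change of at least 1.5-fold, 303 higher and 465 lower, and 10 passed after Benjamini-Hochberg adjustment.

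The inflammatory gene lists were called higher after intact matings by camera with its preset correlation of 0.01 and by fry, which asks whether a list moves on balance one way, but not by camera with an estimated correlation. Among neutrophil and monocyte chemokines, 6 of 14 measured members rose and 8 did not pass when adjusted over the list alone, and 1, Cxcl5, passed over all clusters; the median log2 difference was 0.59 (camera adjusted p = 1.21e-06 over 32 lists, adjusted p = 0.184 with an estimated correlation, fry adjusted p = 0.0267). Cxcl1 and Cxcl2, the main ligands of the neutrophil receptor, had log2 differences of 1.39 (SE 0.26, adjusted p = 0.0957) and 1.74 (SE 0.42, adjusted p = 0.157) and did not pass over all clusters, although all 4 intact arrays lay above all 4 SVX/VAS arrays. Ccl2, which attracts monocytes, had a log2 difference of 1.61 (SE 0.41, adjusted p = 0.172). Of 26 inflammatory cytokines and leukocyte growth factors, 11 rose, 2 fell and 13 did neither over the list alone, and 2, Il1b and Csf3, passed over all clusters (median 0.27, camera adjusted p = 1.21e-06, adjusted p = 0.0924 with an estimated correlation, fry adjusted p = 0.00899). The 2 lower members were Il18, with a log2 difference of -1.13 (adjusted p = 0.0526 over all clusters), and Tgfb3, with -0.73 (adjusted p = 0.0672), both named after their values were seen. Of 25 members of the NF-kB family and its feedback inhibitors, 16 rose and 9 did not pass over the list alone, while 0 passed over all clusters in limma and 17 had an unadjusted p under 0.05. The smallest p was that of Zc3h12a, an RNase that degrades cytokine transcripts (log2 difference 0.83, adjusted p = 0.0754). The median of this list was 0.37 (camera adjusted p = 2.74e-12, adjusted p = 0.184 with an estimated correlation, fry adjusted p = 0.0196). Tnfaip3, the feedback inhibitor A20, had a log2 difference of 1.52 (adjusted p = 0.0867). Members below the median cluster numbered 6 of the chemokines, 14 of the cytokines and 1 of the NF-kB list. For each of these lists the real grouping gave a larger difference in the mean of the members than the other splits of the 8 arrays into 4 and 4 (exact permutation test, two-sided, p = 0.0286, the smallest that 35 splits allow, and 0.153 after adjustment over 32 lists).

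Markers of neutrophils and antimicrobial proteins were called in the same way. Of 32 measured markers, 3 rose, 1 fell and 28 did neither over the list alone, 0 passed over all clusters in limma (8 at an unadjusted p under 0.05, 7 of them higher), and the median log2 difference was 0.12 (camera adjusted p = 0.00098, adjusted p = 0.0924 with an estimated correlation, fry adjusted p = 0.0135). Hdc, the histamine-forming enzyme, had the smallest p, with a log2 difference of 0.90 (adjusted p = 0.0917), and Ly6g, the classical surface marker, was the lower member, at -0.37 (adjusted p = 0.2). Of the 32 markers, 23 had a mean below the median cluster. Among 32 antimicrobial and acute phase proteins, 3 rose and 29 did not pass over the list alone, 18 lay below the median cluster, and the median was 0.14 (camera adjusted p = 0.000217, adjusted p = 0.0924 with an estimated correlation, fry adjusted p = 0.00899). Those that rose were Pglyrp1, which binds bacterial peptidoglycan (log2 difference 0.78, adjusted p = 0.0555), Chil1, a chitinase-like protein (1.91, adjusted p = 0.0917), and Nos2, the inducible nitric oxide synthase (1.06, adjusted p = 0.159).

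Of the 19 immune genes fixed before the data were examined, 2, Csf3 and Il1b, passed over all clusters in limma, and 14 had an unadjusted p under 0.05. Lif had a log2 difference of 1.03 (95% confidence interval 0.67 to 1.39, adjusted p = 0.0598), Tnf of 1.26 (0.71 to 1.82, adjusted p = 0.106), and Ptgs2, the inducible prostaglandin synthase, of 1.20 (0.39 to 2.01, adjusted p = 0.231). Il1a and Tgfb1 had log2 differences of 0.71 and 0.54 (adjusted p = 0.22 and 0.146). Il6 had 0.68 (adjusted p = 0.17), at a mean of only 3.30 after intact matings. For Tlr4, the receptor for bacterial lipopolysaccharide named in the title of the study, the log2 difference was -0.45 (95% confidence interval -0.74 to -0.16, adjusted p = 0.209), and all 4 intact arrays lay below all 4 SVX/VAS arrays. Its co-receptors Cd14 and Ly96 had log2 differences of 0.37 and 0.22 (adjusted p = 0.422 and 0.698) with overlapping groups. Myd88, the adaptor downstream, had -0.04 (adjusted p = 0.92), and 0.01 without intact replicate 3. Csf2, Ccl20 and Foxp3 had log2 differences of 0.29, 0.25 and 0.41 and Il10 of -0.12, none of which passed (adjusted p = 0.355, 0.505, 0.294 and 0.705). Of these, Csf2, Foxp3 and Il10 lay below the median cluster, at means of 4.27, 4.91 and 3.25 after intact matings. For Csf2 all 4 intact arrays lay above all 4 SVX/VAS arrays, and its other row had a log2 difference of 0.45.

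**Figure D2:**
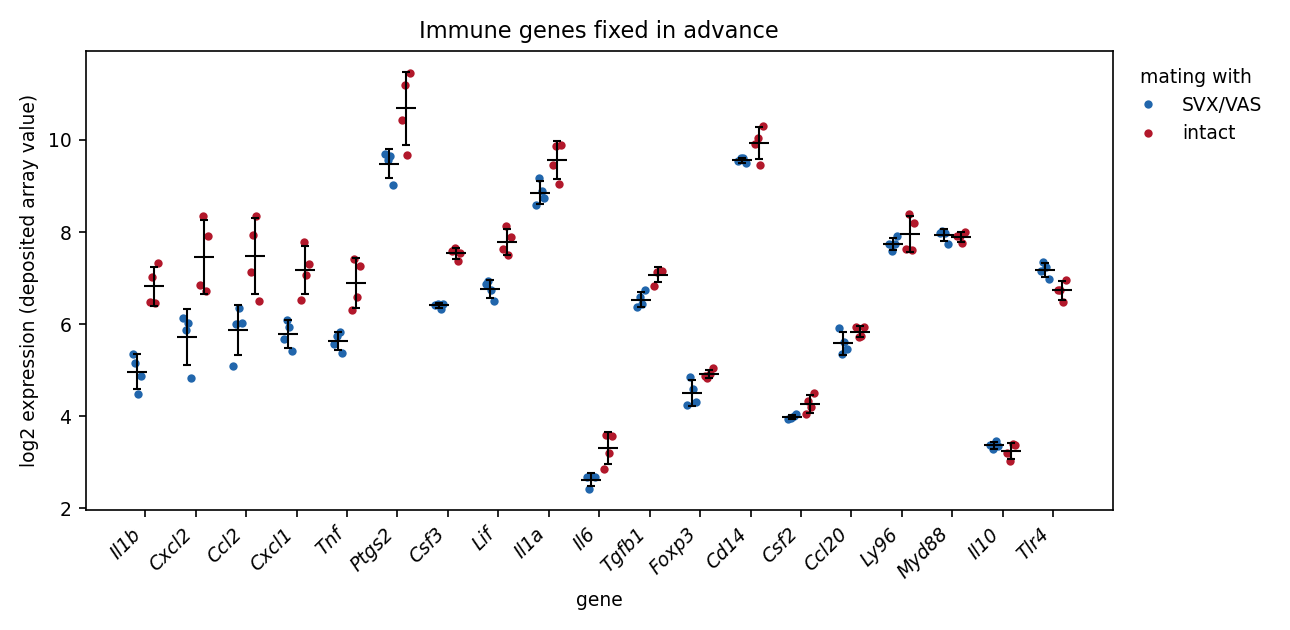
Log2 expression of each array for the 19 immune genes fixed in advance, SVX/VAS in blue and intact in red, with the mean and SD of 4 arrays in black; the x axis lists genes, ordered by their difference. The groups of Csf3 and Il1b are apart, and so are those of several genes that did not pass, such as Cxcl1, Tnf, Lif and Tlr4. Those of Myd88 overlap at 7.90 ± 0.10 and 7.93 ± 0.13.

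The list of the TLR4 receptor complex and toll-like receptor adaptors did not pass. Of 23 members, 1, Tlr1, was lower over the list alone (log2 difference -0.54, adjusted p = 0.116 over all clusters), the median was -0.05 and the camera adjusted p was 0.67. The mean of this list changed sign with quantile normalization, from -0.017 to 0.0041.

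Of the 18 circadian clock genes, 5 were lower over the list alone, 1, Nr1d2, passed over all clusters, and the median was -0.10 (camera adjusted p = 0.00339, adjusted p = 0.263 with an estimated correlation, fry adjusted p = 0.0267). Cry2, a repressor of the clock, and Dbp, one of its output genes, both named after their values were seen, were also lower over the list alone, at log2 differences of -0.51 and -0.52 (adjusted p = 0.149 and 0.166 over all clusters). For the antimicrobial, neutrophil and clock lists too, the real grouping gave the largest difference of the 35 splits (exact permutation p = 0.0286, and 0.153 after adjustment).

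For 3 more lists camera with its preset correlation gave an adjusted p under 0.05, but neither an estimated correlation nor fry did. Of 22 glycolysis and hypoxia-responsive genes, 1, Car9, a carbonic anhydrase of hypoxic cells, rose over the list alone (log2 difference 0.68, adjusted p = 0.109 over all clusters). The median was 0.17 (camera adjusted p = 0.000695, adjusted p = 0.735 with an estimated correlation, fry adjusted p = 0.323), and without intact replicate 4 the mean log2 difference fell from 0.20 to 0.12, with a camera adjusted p of 0.0884. Of 21 genes of the unfolded protein response and protein folding, 2 rose over the list alone, among them Herpud1, a component of the degradation machinery of the endoplasmic reticulum (log2 difference 0.63, adjusted p = 0.148), and the median was 0.11 (camera adjusted p = 0.0102, adjusted p = 0.735 with an estimated correlation, fry adjusted p = 0.302). Without intact replicate 4 or SVX/VAS replicate 1 its camera adjusted p was 0.122 or 0.0756. Of 30 interferon-stimulated genes 0 passed over the list alone in limma and 6 had an unadjusted p under 0.05, all higher. Isg15 had the smallest unadjusted p, at 0.0028 (log2 difference 0.41), and the median was 0.10 (camera adjusted p = 0.0225, adjusted p = 0.835 with an estimated correlation, fry adjusted p = 0.461). Its mean log2 difference of 0.12 fell to 0.079, 0.078 and 0.094, and its camera adjusted p was 0.176, 0.293 and 0.105, without intact replicate 2, intact replicate 4 and SVX/VAS replicate 3.

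In total camera called 9 of 32 lists, 8 higher and 1 lower. None of the 9 passed with an estimated correlation, where 5 lists had an unadjusted p under 0.05. Fry called 6, all among the 9. Counts of this size with the preset correlation also arose in other splits of the arrays: 12 of the 35 splits, the real one included, called at least 9 lists, whereas for fry the highest count in any other split was 1.

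None of the lists of hormone response, prostaglandins and matrix turnover passed the list test. Of 24 estrogen-responsive uterine genes, 3 rose and 2 fell over the list alone, with a median of 0.09 (camera adjusted p = 0.442). Those that rose were Sprr2d, Sprr2e and, named after its values were seen, Sprr2b (log2 difference 1.33, adjusted p = 0.0568), all of the Sprr2 family, and those lower were Padi4, a peptidylarginine deiminase, and Esr1, the estrogen receptor (log2 differences -0.47 and -0.38, adjusted p = 0.145 and 0.15). Of 23 progesterone-responsive genes 2 rose over the list alone, Acod1, which makes itaconate, by a log2 difference of 0.96 and Ltbp2 by 0.77 (adjusted p = 0.153 and 0.168 over all clusters; list median 0.03, camera adjusted p = 0.67). Of 21 genes of prostaglandin synthesis and signalling, 2 fell over the list alone: Akr1c18, the enzyme that inactivates progesterone, with a log2 difference of -1.25 (SE 0.19, adjusted p = 0.0598), and the prostaglandin E2 receptor gene Ptger4, with -0.69 (adjusted p = 0.0994). The median of that list was -0.04 (camera adjusted p = 0.444). Of 25 matrix proteases and inhibitors, 2 rose and 1 fell over the list alone: Plaur, the urokinase receptor, had a log2 difference of 1.07 and Plat, tissue plasminogen activator, of 0.99, while the metalloprotease Adamts1 had -0.67 (adjusted p = 0.138, 0.173 and 0.188). That list had a median of -0.05 but a mean of 0.03 and an upward test (camera adjusted p = 0.802).

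The proliferation, early response, lymphocyte chemokine and adhesion lists did not pass either with all 8 arrays. Of 32 genes of DNA replication and mitosis, 0 passed over the list alone in limma and 3 had an unadjusted p under 0.05, all lower. The median was -0.16 (camera adjusted p = 0.0677, and under 0.05 in 5 alternatives, lowest at 0.00054 without intact replicate 3), and Ccnb1, cyclin B1, had the smallest unadjusted p, at 0.00275 (log2 difference -0.71). Of 20 immediate early genes, 3 rose and 1 fell over the list alone, with a median of 0.05 (camera adjusted p = 0.0786, and 0.0274, 0.0458 and 0.0487 without SVX/VAS replicate 2, intact replicate 1 and intact replicate 3). Fos, a subunit of the AP-1 transcription factor, had a log2 difference of 0.91 (adjusted p = 0.0567), while Jun, its partner, had -0.56 (adjusted p = 0.168). Of 21 lymphocyte and other chemokines, 1, Cxcl10, rose and 1, Ccl21a, fell over the list alone, at log2 differences of 0.97 and -0.71 (adjusted p = 0.191 and 0.154), with a median of 0.14 (camera adjusted p = 0.0637, and under 0.05 in 8 alternatives, lowest at 0.00649 without SVX/VAS replicate 4). Of 12 endothelial adhesion molecules 0 passed over the list alone in limma and 2 had an unadjusted p under 0.05, and Icam1, which binds leukocytes, had an unadjusted p of 0.00528 (log2 difference 0.83; list median 0.02, camera adjusted p = 0.67).

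Markers of the cell types of the uterus and of leukocytes other than neutrophils did not pass the list test with all 8 arrays. Leaving out 1 array gave calls for some. Without intact replicate 3 the camera adjusted p was 0.0102 for endothelial, 0.0237 for stromal and 0.0301 for epithelial markers. It was 0.0425 for stromal markers without SVX/VAS replicate 1, 0.00802 for smooth muscle without intact replicate 1 and 0.0453 for mast cells and eosinophils without intact replicate 2. Of 25 epithelial markers, 2 rose, Lif and Wnt7b, and 2 fell, Tmprss2 and Krt18, over the list alone (log2 differences 1.03, 0.62, -0.44 and -0.41). Stromal fibroblast markers had a median of -0.14 (camera adjusted p = 0.373), with Fbln1 at -0.28, and endothelial cell markers a median of -0.10 (adjusted p = 0.292), with Flt1 at 0.48. Smooth muscle markers had a median of 0.01 (adjusted p = 0.734), with Lmod1 at 0.22. Macrophage and dendritic cell markers had a median of -0.02 (adjusted p = 0.999), where the mean was also below 0 but the test pointed upward, with Xcr1 at 0.38. Markers of T, NK and B cells had a median of 0.07 (adjusted p = 0.67), with Foxp3 at 0.41, those of mast cells and eosinophils 0.10 (adjusted p = 0.0748), with Tpsb2 at 0.46, and those of red blood cells 0.10 (adjusted p = 0.471), with Hba-a2 at 0.35. Adipocyte and mesentery markers had a median of 0.06 (adjusted p = 0.734), with Adipoq at 0.27, and ovary and oviduct markers 0.06 (adjusted p = 0.66), with Inha at 0.34. None of the genes named after a median here passed over all clusters.

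Transcripts of the male were examined because, per the labels, only intact matings exposed the females to seminal fluid. Of 29 sperm and spermatid transcripts 0 passed over the list alone in limma and 5 had an unadjusted p under 0.05, 4 of them higher. The median log2 difference was 0.06 (camera adjusted p = 0.309), and Prm1, protamine 1, had the smallest unadjusted p, at 0.00726 (log2 difference 0.39, at a mean of 4.82 after intact matings, below the median cluster). Seminal vesicle and prostate transcripts had a median of -0.0080 and a mean of 0.0028 (adjusted p = 0.972), with Spink8 at 0.38. Epididymis transcripts had a median of 0.05 (adjusted p = 0.316), with Adam28 at 0.43, and Y-linked transcripts a median of -0.03 (adjusted p = 0.972), with Kdm5d at -0.21. Most members of these lists lay below the median cluster, 24 of 29 for sperm, 17 of 19 for seminal vesicle and prostate, 15 of 19 for epididymis and 7 of 8 for the Y-linked list.

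**Figure D3:**
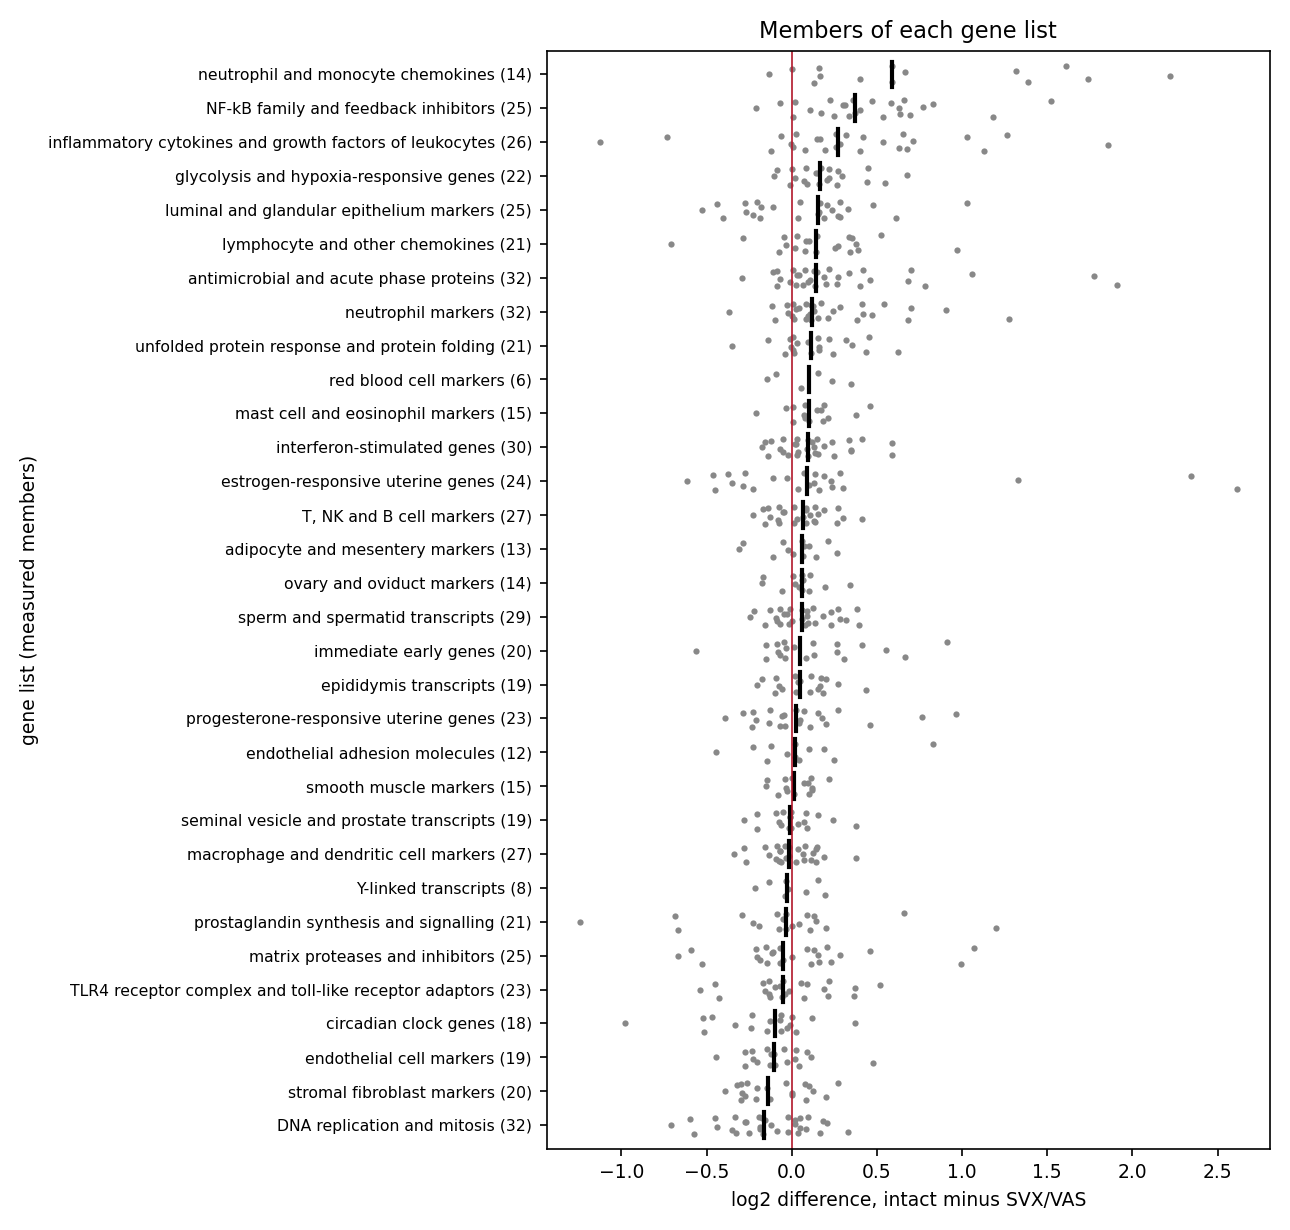
Log2 difference, intact minus SVX/VAS, of each measured member (grey points) of the 32 gene lists, with the median of each list as a black bar and the number of members in parentheses; the red line marks no difference. Medians run from 0.59 for neutrophil and monocyte chemokines to -0.16 for DNA replication and mitosis.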

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

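The test of clock genes in the last paragraph of this part was chosen after the result was seen, and widened from 8 to 16 genes after a first look. For each of the named genes and the 2 unnamed clusters described under other observations, the 4 arrays of each group were searched for 1 array far from the other 3, by Dixon's ratio of the gap to the range against its 95% critical value. Of 200 groups tested, 12 held such an array, where chance gives about 1 in 20 groups, or 10. Of the 12, 4 lie in SVX/VAS replicate 4, 4 in SVX/VAS replicate 2 and 1 in each intact array.

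In SVX/VAS replicate 4, Tnip3 was at 7.68 (others 8.04 to 8.05), Nfkbie at 5.03 (others 5.62 to 5.71), Myd88 at 7.74 (others 7.99 to 8.02) and Bhlhe41 at 5.25 (others 4.66 to 4.76). In SVX/VAS replicate 2, Sprr2d was at 8.58 (others 7.80 to 7.93) and Sprr2e at 7.13 (others 6.42 to 6.48), both still below all intact arrays, Ly6g was at 6.46 (others 6.27 to 6.30) and Il6 at 2.42 (others 2.69 to 2.71). Among the intact arrays, Peg10 was at 11.69 in replicate 2 (others 11.43 to 11.46), Tgfb1 at 6.83 in replicate 1 (others 7.14 to 7.16) and Wnt7b at 6.97 in replicate 3 (others 7.19 to 7.22).

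Nr1d2 was at 6.41 in intact replicate 4, while the other intact arrays lay between 6.01 and 6.07, and all of them were below the SVX/VAS mean of 7.11 ± 0.06 (SD, n = 4). The fall of Nr1d2 and of Dbp (log2 difference -0.52) could arise if the intact females had been collected at another phase of the daily clock. The median log2 difference of the other 16 clock genes was -0.066 (95% bootstrap interval over genes -0.24 to -0.0093), less than the fall of Dbp. A phase shift and a change by mating with intact rather than SVX/VAS males, the designed difference between the groups, cannot be told apart here. What keeps it open is that 5 of the 18 clock genes, Cry2 and Bhlhe41 (-0.51 and -0.47) among them, were lower over the list alone while 13 were not. A phase shift also need not move all clock genes alike.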

How the results depend on the processing

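The stromal covariate was chosen after the data were seen; the other alternatives were planned. All 34 called clusters kept their sign in each refit that tested them, but their number past the threshold did not: from 34 it became 54 with quantile normalization, 77 with array weights, 173 with trend and robust estimation (135 at least 1.5-fold), 358 among rows above the median level (214), 233 among rows with 1 symbol (169), 17 with the stromal covariate, and 10 with the methods' t-test and Benjamini-Hochberg (6). The counts at least 1.5-fold are the same where none is given. The kept sign is no evidence of stability. In each of the 34 the groups do not overlap, so neither leaving out 1 array nor weighting arrays can reverse it. The block, the row filters, the trend and the t-test leave the group difference itself unchanged. After Benjamini-Hochberg adjustment, 10 passed in the authors' deposited table. Fewer rows tested is part of the rise among rows above the median level and rows with 1 symbol; for the others the cause was not tested. The number past the threshold was 31 with centring on the median. At an unadjusted p under 0.05 and 1.5-fold, the methods' t-test and the authors' deposited table both gave 768. The deposited p-values match those of this t-test on the same values, so they are not separate checks. Of the 34, quantile normalization kept 33, centring 30, array weights and trend and robust estimation 34 each, the t-test 6 and the stromal covariate 15. The share of higher calls moved with the filter and the trend, from 21 higher and 13 lower to 144 and 214 above the median level and 68 and 105 with the trend. Leaving out 1 array left no lower call in 6 of the 8 fits (41 higher and 9 lower without intact replicate 3, 11 and 10 without intact replicate 4).

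Replicate numbers do not pair the samples: deviations of same-numbered arrays correlated at 0.068, 0.026, -0.021 and -0.033. With the replicate block 0 clusters passed in limma, at either fold limit, and 4620 had an unadjusted p under 0.05, against 4925 without it; the block leaves fewer degrees of freedom.

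Leaving out 1 array gave 2 to 50 clusters at both fold limits (2, 4, 50 and 21 without intact replicates 1 to 4, and 3, 9, 2 and 2 without SVX/VAS replicates 1 to 4), and 7 to 15 lists, with 7 without intact replicate 4 and 15 without intact replicate 3; fewer samples are part of the falls, and for the rises the cause was not tested. Of the 32 lists, 9 were called by camera, 0 with an estimated correlation (5 at an unadjusted p under 0.05), 6 by fry, and 9 or 10 under the block, both normalizations, array weights, the mean of all rows and the stromal covariate. Lists that were not called gained a call in 22 of 368 values, the lymphocyte chemokines in 8 settings, DNA replication and mitosis in 5, immediate early genes in 3, stromal markers in 2 and endothelial cell, epithelial, smooth muscle and mast cell markers in 1 each.

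Reversals arose only among uncalled results, and the cause was not tested. When 1 array was left out, the log2 difference of Myd88 ran from -0.10 to 0.011. Sign changes were also seen in the mean log2 difference of the TLR4 complex (-0.057 to 0.018; 0.0041 with quantile normalization), matrix proteases (-0.011 to 0.11), endothelial adhesion molecules (-0.045 to 0.14), macrophages and dendritic cells (-0.076 to 0.060; 0.0042 with quantile normalization, 0.040 with the stromal covariate), stromal fibroblasts (-0.21 to 0.061), smooth muscle (-0.086 to 0.21), fat and mesentery (-0.0053 to 0.037), seminal vesicle and prostate (-0.029 to 0.031; -0.00018 with the stromal covariate) and Y-linked transcripts (-0.035 to 0.050; 0.0019 with quantile normalization). The 25 genes named by the largest changes kept their sign in all 425 values under alternatives and their side of the threshold in 211. The groups of these 25 do not overlap, so leaving out 1 array could not change their sign. Of the other 73 named genes, 20 passed in at least 1 setting. Signal over background is not in the files. Lists with most members below the median cluster include the called cytokines (14 of 26), antimicrobial proteins (18 of 32) and neutrophil markers (23 of 32), and the uncalled male-tract, mast cell, lymphocyte, red blood cell, ovary and fat lists.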

Other observations

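All lists, tests of explanations and the fry count of splits in this part were chosen after the data were seen; only the counts of clusters and of camera lists over splits of the arrays were planned. For neutrophils, the demand that the interval lie above 0 was added after the interval had been seen. By the median alone the markers above the median cluster had met the prediction of an influx, and this demand turned that result into an open one. Beyond the lists fixed in advance, 6 lists were built because their genes stood out, so neither their counts nor their p-values, adjusted over these 6, are independent evidence of a difference. Of 20 enzymes of cholesterol synthesis, 16 rose over the list alone, 6 passed over all clusters and 18 had a positive difference, with a median log2 difference of 0.97 (camera adjusted p = 3.78e-25, adjusted p = 0.0453 with an estimated correlation, fry adjusted p = 0.000683). Cyp51 and Msmo1, which remove methyl groups from lanosterol, had log2 differences of 1.62 and 1.39 (adjusted p = 0.0526 for both over all clusters), while Ebp, which acts late in the pathway, was at -0.11. Of 18 enzymes of fatty acid synthesis and desaturation, 7 rose over the list alone, among them Scd2, Elovl6 and Fasn (log2 differences 0.83, 0.65 and 0.44), with a median of 0.14 (camera adjusted p = 0.000219, adjusted p = 0.206 with an estimated correlation, fry adjusted p = 0.0139). Of 10 targets of the oxysterol receptor LXR, 2 were lower over the list alone, the cholesterol exporter Abca1 at -0.61 and Mylip, a ubiquitin ligase, at -0.43. The LXR list did not pass (camera adjusted p = 0.0583, and 0.245 with an estimated correlation). It passed in 5 alternatives, with camera adjusted p from 0.0168 without intact replicate 2 to 0.0454 with array weights.

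Of 24 targets of FOXO transcription factors, 13 were lower over the list alone and 1, Sesn3, passed over all clusters, with a median of -0.33 (camera adjusted p = 7.33e-12, adjusted p = 0.0706 with an estimated correlation, fry adjusted p = 0.00192). Txnip and Trp53inp1 had log2 differences of -0.99 and -0.92 (adjusted p = 0.0568 and 0.0555 over all clusters). Of 30 ribosome biogenesis factors, 9 rose and 1 was lower over the list alone, with Tbl3 at 0.75 and Ltv1 at 0.48 and a median of 0.16 (camera adjusted p = 1.1e-05, adjusted p = 0.0914 with an estimated correlation, fry adjusted p = 0.00656). Among 17 ligands and receptors of the interleukin 1 family, 7 rose and 3 were lower over the list alone: the epithelial ligands Il1f6 and Il1f9 had log2 differences of 1.62 and 1.47, and Il18 of -1.13 (camera adjusted p = 0.00505, adjusted p = 0.224 with an estimated correlation, fry adjusted p = 0.0515).

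Over the 35 splits of the 8 arrays into 4 and 4, the real one called 34 clusters, with and without the limit of 1.5-fold, and the highest of the others called 1; only 1 split, the real one, gave as many. For these counts the rank of the real split argues against chance, at a share of 0.0286 with all 8 arrays. That share is the smallest that 35 splits allow and was not adjusted for the other counts over splits, so chance is not excluded. Leaving out 1 array gave 2 to 50 clusters. For lists called by camera with the preset correlation chance cannot be excluded: the real split called 9, the highest other 15, and 12 splits called at least as many. The split with 15 put SVX/VAS replicate 2 with intact replicates 1, 2 and 4. For lists called by fry, the real split gave 6 and the highest other 1, and again only 1 split, the real one, gave as many.

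The rise of cholesterol synthesis enzymes was weighed because 6 of them passed over all clusters. The median of all 20, 0.97, ran from 0.86 without intact replicate 4 to 1.06 without intact replicate 3, but these are genes chosen for the pattern, so this decides nothing about single arrays. If the intact scrapings held a larger share of epithelium, epithelial markers ought to rise by at least as much as the enzymes. Their median was 0.16 with Lif. Without Lif it was 0.103, with an upper 95% bootstrap limit over genes of 0.20, below the lower limit of 0.62 for the enzymes. The epithelial list was fixed in advance, but the enzymes were chosen for their rise, which raises their limit. Both limits resample genes and not pools, so they leave out the uncertainty of the difference between groups. The gap therefore argues against a share of epithelium only as the sole cause, and only for these chosen enzymes. Mating with intact rather than SVX/VAS males, the designed difference between the groups, and a change within another cell type stay open, as untested. With only these groups, components of what intact males deliver cannot be told apart.

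For the chemokine, cytokine and NF-kB lists, the median of their 65 members was 0.37, and the lowest on leaving out 1 array was 0.318, without intact replicate 4, which argues against a single array as the cause. Whether the endometrium changed its expression or more neutrophils had entered it cannot be told apart here. The 9 neutrophil markers above the median cluster had a median of 0.410, but with a 95% bootstrap interval over genes of -0.11 to 0.90. All 32 had 0.12 (0.081 to 0.24), below the lower limit of 0.26 for the inflammatory genes. What keeps it open is that the interval of these 9 spans both 0 and the rise of the inflammatory genes, and that 23 of the 32 markers lie below the median cluster, as do 14 of the 26 cytokines. A response of the tissue to mating with intact males and an influx of leukocytes may both contribute.

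Marker means varied between arrays of a group. The mean of the stromal markers was 7.25 in intact replicate 1 and 8.01, 8.08 and 7.61 in intact replicates 2, 3 and 4, against 7.53 to 8.08 in SVX/VAS. The mean of the smooth muscle markers was 6.56 in intact replicate 1 and 7.05 to 7.46 in the other intact arrays, against 6.78 to 7.28 in SVX/VAS.

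Among clusters without a gene symbol, the largest differences were those of 17514343 and 17388663, and the files do not pair them with a name. The first had a log2 difference of 3.26 (adjusted p = 0.305) and stood at 10.29 in intact replicate 2, at 4.39 to 5.52 in the other intact arrays and at 2.68 to 3.14 in SVX/VAS. The second had a log2 difference of 2.61 (adjusted p = 0.159) and stood at 12.89 in intact replicate 2, at 9.24 to 10.97 in the other intact arrays and at 8.04 to 8.79 in SVX/VAS.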
